A study of Homo sapiens with 6 samples.

How the data were processed

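The 6 arrays held biotin-labelled material from total RNA of HaCaT cells, 3 mock-irradiated cultures and 3 cultures irradiated with 20 Gy of X-rays at 1.15 Gy per min, collected after 48 h. Per the labels' protocols, cells were grown in DMEM with fetal bovine serum, RNA was isolated on RNeasy columns (the design text names Trizol for collection), and it was amplified and labelled with the Ambion WT Express kit. Groups and replicate numbers were taken from the sample titles.

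The authors deposited log2 signals in a gene-level table and an exon-level table. Per the submitters' processing notes the gene-level values came from RMA, which corrects background, quantile-normalizes probes and summarises them, and per the file headers the exon-level log2 values came from an SST-RMA alternative splicing workflow, with signal columns only. The versions, the array library files and the genome build are not given in the sources used here. The gene-level table had 70523 features, of which 67528 were transcript clusters, and the exon-level table held 914585, of which 573909 were probe selection regions (exon parts) and 339146 junctions. The 2995 features that both tables hold had a largest difference of 0 between the tables, so for these both held the same values. The gene-level values may thus also come from SST-RMA and not from plain RMA, which the sources used here do not settle. Fold changes are those of the deposited signals. Array medians ran from 4.53 to 4.66 at the gene level and from 5.49 to 5.53 at the exon level. Deposited values were used without further scaling in the planned tests.

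The platform annotation listed 25324 clusters with symbols, 23781 with 1 symbol and 1543 with several, and genes were named from the former only, leaving 43747 clusters unnamed here. Symbols were updated through the gene tables of GRCh38.p14, 21497 by gene number, 1974 by symbol and 306 by a unique synonym, with 4 kept as given, and no coordinates were used. Where 528 symbols had several clusters, the cluster with the highest mean over the 6 arrays stood for the gene in lists and in tests of genes with a symbol (22411 genes), and 0 of these symbols had clusters going both ways at unadjusted p under 0.05. The 6 values of 2371 clusters equal those of another cluster, 690 of these being named, so such clusters are not independent. Genes with near-identical copies, such as histones, 5S rRNA pseudogenes and Y RNA pseudogenes, can share probe signal. NEAT1 was not analysed here. Of the items chosen in advance, 1 gene and 1 list are not reported here, and that list still entered every test and count of lists. No gene was paired with exon-level features, so differential exon use was not analysed here.

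Differences were tested with limma 3.58.1 in R 4.3.3 (statmod 1.5.0 and data.table, version 1.17.8), with lmFit and eBayes and a variance trend, two-sided, Benjamini-Hochberg adjusted, and a threshold of 0.05. The planned fit had no block, and a fit with the replicate number as a block was also planned. The replicate numbers come from the sample titles and were taken to pair the cultures, since deviations from the group means correlated at 0.523, 0.644 and 0.705 within numbers 1, 2 and 3, against -0.555 to 0.0721 between different numbers. The first principal component (48.6% of variance) separated replicate 3, the second (20.7%) replicates 1 and 2, and the next (16.1%) irradiated from mock arrays. Correlations between arrays ran from 0.977 to 0.993. The labels call the cultures biological replicates and do not say whether they were grown on separate days.

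After these tests had called 0 clusters, a paired limma test over the 9324 genes with a mean above the brightest of 23 background control sets (6.01) was added, and likewise one over exon-level features above that limit. These tests, their alternatives, the list fit combining block and quantile normalization, and the histone list with H2BC10 were chosen after seeing the data. The gene lists, the rule for named genes, the designs and the other settings were chosen before the data were examined. The 22 fixed lists held 424 entries, 346 of them matched to a measured gene (older symbols only where unique, which left out H2BC10), and covered DNA damage, cell cycle, interferon, secretory, keratinocyte, metabolic and stress genes, long non-coding RNAs and markers of other cell types. Lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry. Interferon and histone lists were also set against 10000 random lists matched on signal. Proportions of coding and non-coding genes were compared with Fisher's exact test.

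Named genes were the 12 increases and 12 decreases past the threshold with the largest change, 1 symbol and no overlap between groups, from each list up to 4 genes past the threshold or otherwise the 2 with the smallest p, 11 genes fixed in advance and the 5 increases and 5 decreases among non-coding genes. As under 5 clusters passed the threshold, the ranking used the unadjusted p of the unpaired test. Other genes named are said to be chosen after their values were seen. Other settings chosen in advance were the block, leaving out each replicate, a signal filter, median centring, quantile normalization, eBayes without trend or robust, array weights, an ordinary equal-variance test, fold limits, the mean of clusters per symbol, and the list tests and background. Leaving out 1 array refitted the unpaired model with its partner still in, so differences between cultures entered the result. Whole pairs were left out only in the added tests. A filter on detection p-values was not run, since the columns used here hold signals only. Genes on the Y chromosome, XIST and TSIX were left out of the per-gene values. Over 1530 control features the unpaired and paired tests called 0 (93 at unadjusted p under 0.05 in the unpaired limma test). The 92 spike-in sets had a median difference of -0.019 at a median signal of 4.66, below the background limit. The 8 hybridisation and labelling control sets had a median difference of -0.23 at a median signal of 9.38.

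The tests were checked on simulated data with 200 changed genes. Over 67528 clusters the unpaired test recovered 26% of 2-fold and 78% of 4-fold changes and the paired test 41% and 92%. Over 9324 genes above background the unpaired test recovered 42% and 84% and the paired test 98% and 100%, with 7 false calls. The simulation drew the errors of each gene independently and held no signal-dependent shift between arrays. It therefore does not show how many of the 467 genes called on the real arrays are false. In 50 simulated unchanged data sets, 2 had any list past the threshold. These sets held no pair differences and no correlation between genes, whereas the estimated correlation was 0.66 for interferon and 0.79 for mitosis genes. They therefore do not show how often lists of genes that move together pass without a change. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.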

Results

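HaCaT cells, a spontaneously immortalised human keratinocyte line, were profiled 48 h after a single X-ray exposure of 20 Gy, given at 1.15 Gy per min, or after mock irradiation. Each group held 3 cultures that the labels call biological replicates, numbered alike in both groups, and 1 array was run per culture. The arrays measured coding and non-coding RNA at the level of transcript clusters, which stand for genes, and at the level of exon parts and splice junctions. Gene-level signals were deposited on a log2 scale, with array medians from 4.53 to 4.66, and between 41.3% and 41.8% of genes with a single symbol lay above the brightest background control set on each array. The number of arrays limits the precision of every value. The design asks which mRNAs and long non-coding RNAs differ between irradiated and mock-irradiated keratinocytes.

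Irradiated cells carried more interferon-stimulated transcripts, with a median difference of 1.08 on the log2 scale (2.11-fold) over the 28 measured genes of that list, 28 of which were higher. Genes for replication-dependent histones (median -0.49), cholesterol synthesis (median -0.21) and mitosis (median -0.20) were lower, and secreted inflammatory and NF-kB genes were higher (median 0.16). These 5 of 22 lists passed limma's camera test with its preset correlation of 0.01, and 0 lists passed with a correlation estimated from the data. Other splits of the 6 arrays into 3 and 3 moved up to 11 lists. Those that part every pair of cultures with the same number moved up to 6. Among single genes, DKK1, a secreted WNT antagonist, rose 4.21-fold, from 8.70 ± 0.35 to 10.78 ± 0.54 (log2 signal, SD, n = 3 per group), and FASN, the fatty acid synthase, fell by 0.98, from 11.30 ± 0.17 to 10.33 ± 0.36, in a paired limma test added after the data were examined.

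No transcript cluster of 67528 passed the planned unpaired limma test (0 called, lowest adjusted p = 0.510), and 4822 had an unadjusted p under 0.05 against 3376.4 expected by chance. With the replicate number as a block, 0 clusters were called (lowest adjusted p = 0.210) and 10237 had an unadjusted p under 0.05. Over all 22411 genes with a single symbol, bright or dim, the paired limma test also called 0 (lowest adjusted p = 0.0759). A narrower test was then added, once the data had been examined and both planned tests had called 0: the paired limma test over the 9324 genes with a single symbol whose mean lay above the brightest background control set (6.01). It called 467 genes, 121 higher and 346 lower, with a lowest adjusted p of 0.0093, while the unpaired test over the same genes called 0 (312 at unadjusted p under 0.05). Adjusted p-values of single genes are from this added test unless another is named. Of the called genes, 27 were at least 2-fold higher and 1, the long non-coding RNA LINC02035, at least 2-fold lower. The number of decreases depended on scaling. On the deposited values 121 of 467 calls were increases (25.9%), after quantile normalization 119 of 203 (58.6%, 107 increases and 84 decreases being shared), after cyclic loess 116 of 179 (64.8%) and with each array centred on these genes 180 of 269 (66.9%), so decreases went from 346 to 84, 63 and 89. Single genes said to fall carry adjusted p-values from the deposited values, and their calls after rescaling are not given here. Without pair 1, 2 or 3 the test called 251, 66 and 140 genes, of which 176, 58 and 109 were among the 467.

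**Figure D1:**
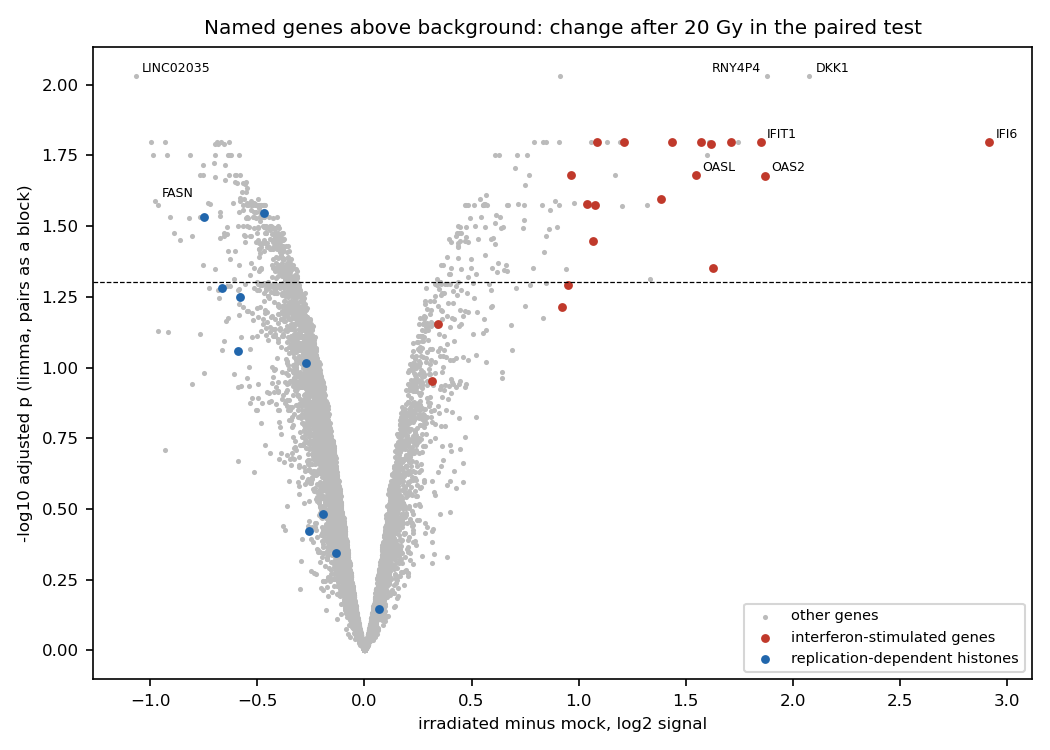
Paired limma test over 9324 genes above background. The x axis is irradiated minus mock (log2 signal, 3 arrays each), the y axis is minus log10 of the adjusted p, each point is 1 gene, and the dashed line is an adjusted p of 0.05; interferon-stimulated genes (red) lie to the right, with IFI6 farthest at 2.92, and most replication-dependent histone genes (blue) lie to the left.

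Interferon-stimulated genes, which are induced through interferon receptors or directly by nucleic acid sensors, formed the group with the strongest shift. All 28 measured genes of the 30 fixed were higher, 27 of them in every pair, and the pair medians were 0.97, 1.58 and 0.65. The list rose in the camera test (adjusted p = 8.73e-16), with an adjusted p = 0.639 with an estimated correlation. Adjusted over the list alone, 11 genes passed the unpaired test and 26 the paired one, against 0 over all genes tested, and 16 of the 20 above background rose in the added test. IFI6, a small interferon-induced membrane protein, rose by 2.92, from 9.22 ± 1.86 to 12.13 ± 2.39 (adjusted p = 0.0160), and by 1.90 without mock replicate 3. OASL rose by 1.55 (adjusted p = 0.0209) and HERC5, the main ligase for ISG15 conjugation, by 1.21 (adjusted p = 0.0160). Of genes chosen after their values were seen, OAS2, a synthetase that activates RNase L, rose by 1.87, IFIT1, which binds foreign RNA ends, by 1.85, IFI44 by 1.71 and RIGI, a cytosolic RNA sensor, by 1.38. IFIT1 lay at 5.57 in mock replicate 2 and 5.90 in mock replicate 3, below the background limit. The size of the IFIT1 difference is thus not determined. The list's median lay at percentile 100 of 10000 random lists matched on signal, whose central 99% ran from -0.14 to 0.044. Those lists were matched on signal only, and the estimated correlation within this list was 0.66. Their range thus leaves out the spread of genes that move together. Class I antigen presentation genes, which also respond to interferon, had a median of 0.0067 but a mean of -0.039 and a camera test pointing down (adjusted p = 0.436), with 7 of 13 higher. HLA-E lay at -0.12 and HLA-F at -0.13, and neither passed.

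**Figure D2:**
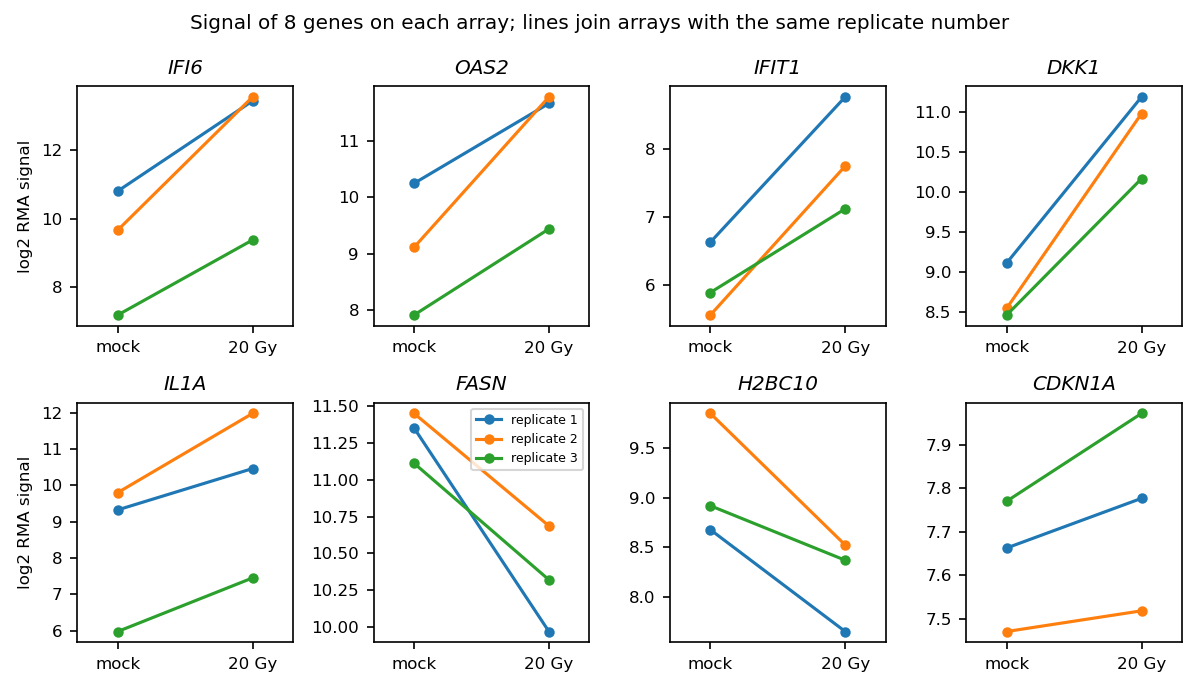
Log2 signal of 8 genes on each array (y axis) for mock and 20 Gy (x axis), with a line joining the arrays of the same replicate number. IFI6, OAS2, IFIT1, DKK1 and IL1A are higher and FASN and H2BC10 lower in all 3 pairs, while CDKN1A differs by 0.12 on average.

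Replication-dependent histone genes, whose transcripts end in a stem loop and mostly lack poly(A) tails, were lower after irradiation. Of 29 fixed, 12 were matched to a measured gene, of which 11 were lower, 8 of them in every pair, with pair medians of -0.44, -0.72 and -0.21. The list fell in the camera test (adjusted p = 1.98e-05), with an adjusted p = 0.639 with an estimated correlation, and the median was -0.32 without irradiated replicate 1. Adjusted over the list alone, 0 genes passed the unpaired limma test (2 at unadjusted p under 0.05) and 8 the paired one. H2BC17 fell by 0.75 (adjusted p = 0.0294) and H2BC9 by 0.47 (adjusted p = 0.0285), the 2 of these 10 above background that passed. H2BC10, a fixed member under an older symbol that 2 genes share and so not matched, fell by 0.96 (adjusted p = 0.0267), and by 0.61 without mock replicate 2. With it, in a test added after the data were examined, 12 of 13 genes were lower, 3 of 11 above background passed, and the list had a median of -0.51 and a camera adjusted p of 3.44e-06. H1-2, outside the fixed list and chosen after its value was seen, fell by 0.93. The list's median lay at percentile 0 of 10000 matched random lists (central 99% from -0.20 to 0.075). That range leaves out the correlation within the list, estimated at 0.37.

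Cholesterol synthesis genes were lower in 16 of 16 measured cases, 11 of them in every pair, and the list fell in the camera test (adjusted p = 1.05e-04), with an adjusted p = 0.639 with an estimated correlation. INSIG1, which retains the sterol sensor SCAP in the endoplasmic reticulum, fell by 0.69 (adjusted p = 0.0160) and LSS, the lanosterol synthase, by 0.38 (adjusted p = 0.0434). STARD4, a sterol carrier named after its value was seen, fell by 0.47 (adjusted p = 0.0319) and lay at -0.27 without irradiated replicate 1. These 3 of 16 passed the added test, and adjusted over the list alone 0 passed the unpaired limma test (2 at unadjusted p under 0.05) and 5 the paired one. The list median was -0.40 without irradiated replicate 2, -0.39 without mock replicate 3 and -0.13 without irradiated replicate 3. FASN (fell by 0.98, adjusted p = 0.0258) and ACSL1, which activates long-chain fatty acids (from 9.77 ± 0.0056 to 9.07 ± 0.078, adjusted p = 0.0163), were among the 12 decreases with the smallest unadjusted p in the unpaired test.

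Mitosis genes were lower in 28 of 29 measured cases, 12 of them in every pair, with pair medians of -0.29, -0.31 and 0.013. The list fell in the camera test (adjusted p = 0.00609), with an adjusted p = 0.796 with an estimated correlation. The call was lost after quantile normalization (median -0.089, adjusted p = 0.322), without irradiated replicate 1 (median -0.034, 0.290), without irradiated replicate 3 (median -0.14, 0.0984) and without mock replicate 2, where the list turned upward (median 0.11, 0.840). Against a background of genes above the median signal it was also lost (0.512), with the median unchanged. Without irradiated replicate 2 the median was -0.36. MKI67, the Ki-67 proliferation antigen, fell by 0.40 (adjusted p = 0.0448), with -0.44, -0.45 and -0.30 in the pairs. It was the only one of the 29 to pass the added test. In unpaired fits its difference was -0.010 without mock replicate 2 and -0.052 without irradiated replicate 3. It was -0.76 without irradiated replicate 2 and -0.79 without mock replicate 3. The partner of the array left out stayed in these fits, so the spread between cultures entered them. CCNB1 (-0.040), CDC25C (-0.32) and KIF20A (-0.41) did not pass. DNA replication genes had a median of 0.092 (camera adjusted p = 0.817, 0.945 with an estimated correlation, and 0.00573 against genes above the median signal). Their pair medians were -0.12, -0.027 and 0.43, and GINS1 (0.36) and GINS3 (-0.24) did not pass. Homologous recombination and Fanconi anaemia genes had a median of -0.017 (adjusted p = 0.428), and XRCC3 (0.12) and MRE11 (-0.15) did not pass. Non-homologous end joining genes were lower in 12 of 13 cases (median -0.084, and -0.034 to -0.25 with 1 array left out, adjusted p = 0.0616), and passed with the replicate block (adjusted p = 0.0346, and adjusted p = 0.651 with an estimated correlation), without irradiated replicate 2 (0.00327) and without mock replicate 3 (0.00255). NHEJ1, a ligation factor, fell by 0.32 (adjusted p = 0.0475) with -0.32, -0.32 and -0.33 in the pairs, and lay at -0.15, -0.50, -0.51 and -0.14 without mock 1, irradiated 1, mock 2 and irradiated 2.

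Secreted inflammatory and NF-kB genes associated with senescence were higher in 16 of 22 cases, 11 of them in every pair, and the list rose in the camera test (adjusted p = 0.0282), with an adjusted p = 0.639 with an estimated correlation. The call was lost without irradiated replicate 2 (0.191) and without mock replicate 3 (0.289), and the median was 0.30 without irradiated replicate 3. CXCL8, a neutrophil chemokine, rose by 0.83 (adjusted p = 0.0160) and CCL20 by 0.57 (adjusted p = 0.0266). The mock mean of CCL20 (6.06 ± 0.21) lay just above the background limit, so the size of its difference is not determined. IL1A, chosen after its value was seen, rose by 1.60 (adjusted p = 0.0177) with 1.14, 2.18 and 1.47 in the pairs, and ran from 0.40 without mock replicate 3 and 0.59 without irradiated replicate 2 to 2.85 without irradiated replicate 3. In all 6 of 13 genes above background rose, and adjusted over the list alone 0 passed the unpaired limma test (3 at unadjusted p under 0.05) and 7 the paired one. Mesenchymal and matrix genes were higher in 14 of 17 cases (median 0.15, and 0.086 without mock replicate 3, adjusted p = 0.0616) and passed with the replicate block (adjusted p = 5.62e-04, and adjusted p = 0.578 with an estimated correlation), where fry also called them (0.0186). Their 4 calls among 7 genes above background, chosen after their values were seen, were the matrix proteins FN1 (0.79) and THBS1 (1.32), the cadherin CDH2 (0.56) and the transcription factor SNAI2 (0.55). These 4 were higher in all 3 pairs, while the spread between cultures was wide for FN1 (SD of 1.61 among mock arrays) and single arrays moved the differences. Without mock replicate 3 and without irradiated replicate 3 they were -0.14 and 1.68 for FN1 and -0.50 and 1.51 for CDH2, without irradiated replicate 2 and without mock replicate 2 they were 0.38 and 2.18 for THBS1, and SNAI2 lay at 0.28 without irradiated replicate 1. SPARC and POSTN lay below the signal limit of the added test.

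**Figure D3:**
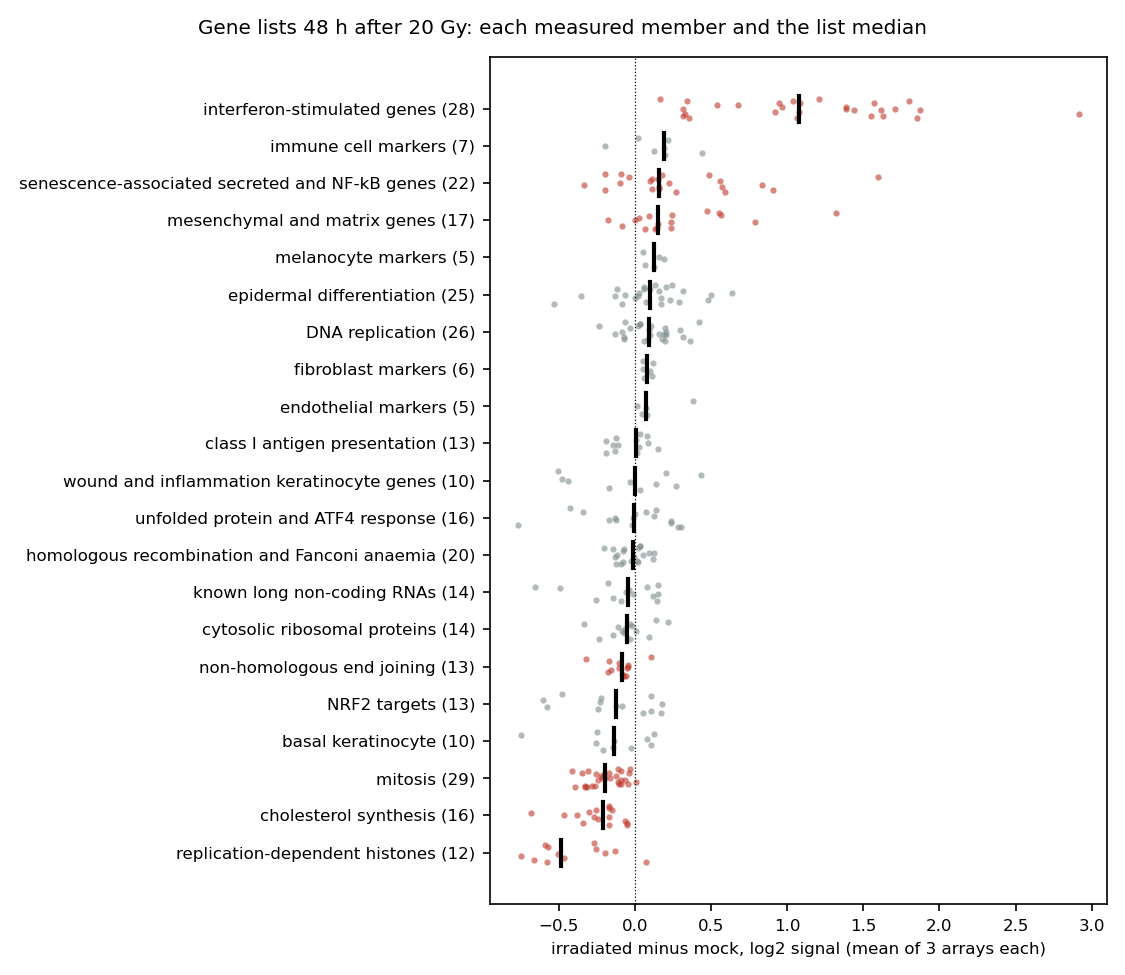
Difference between irradiated and mock (x axis, log2 signal, mean of 3 arrays each) for each measured gene of the fixed lists reported here (y axis, measured genes in brackets). Points are genes, black bars are list medians, and red marks the 7 lists with a camera adjusted p under 0.05 in the fit with the replicate block; interferon-stimulated genes have a median of 1.08 and replication-dependent histones -0.49.

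Other lists did not pass the camera test of the planned fit. DDB2, a damage recognition factor, fell by 0.55 (adjusted p = 0.0261), while PLK2 lay at 0.60 (adjusted p = 0.0605), CDKN1A, the cell cycle inhibitor p21, at 0.12, and MDM2 at 0.023 (adjusted p = 0.864), none of which passed. GDF15 (-0.095) lay below the signal limit and was not in the added test, so the size of its difference is not determined. LMNB1, a lamin lost in many senescent cells, lay at -0.28 (adjusted p = 0.111). Epidermal differentiation genes had a median of 0.098 (camera adjusted p = 0.0933, and 0.796 with an estimated correlation). The members with the smallest p, TGM3 and SPRR2D, lay below the signal limit. That list passed after median centring (0.0403), against genes above the median signal (0.0153), and without irradiated replicate 1 (0.0486), irradiated replicate 2 (0.0108) or mock replicate 3 (0.000879), whereas its median was -0.0023 without mock replicate 1 and -0.012 without mock replicate 2. KRT10 fell by 0.36 (adjusted p = 0.0470) with -0.41, -0.39 and -0.28 in the pairs, although mock arrays spread with an SD of 2.98 and the difference ran from -2.12 without irradiated replicate 3 to 1.36 without mock replicate 3. KRT1 (-0.53) and FLG (0.50), chosen after their values were seen, also passed the added test. In unpaired fits they turned to 2.97 without mock replicate 3 and to -0.11 without irradiated replicate 1 respectively. Such a fit keeps the partner of the array left out, so the spread between cultures enters and the paired call is not tested. Basal keratinocyte genes had a median of -0.14 (adjusted p = 0.436), and KRT15 fell by 0.75 (adjusted p = 0.0434), lying at -0.050 without irradiated replicate 2 and -1.51 without irradiated replicate 3, while KRT5 (-0.21) did not pass and COL7A1 lay below the signal limit. Wound and inflammation genes of keratinocytes had a median of -0.00015 (adjusted p = 0.888), with S100A7 at 0.43 and RNASE7 below the signal limit.

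Unfolded protein and ATF4 response genes had a median of -0.0061 (adjusted p = 0.436). DDIT4, an inhibitor of mTORC1, fell by 0.77 (adjusted p = 0.0209) and lay at -0.48 without irradiated replicate 2 and -0.49 without mock replicate 3, ATF3 lay below the signal limit, and DDIT3 (-0.34) and HERPUD1 (-0.43), chosen after their values were seen, also passed, lying at 0.023 and -0.064 without mock replicate 1. NRF2 targets had a median of -0.12 (adjusted p = 0.514), with ME1 at -0.25 and TXNRD1 at 0.18, and their 1 call, AKR1C3 (-0.61), chosen after its value was seen, turned to 0.26 without irradiated replicate 2. Cytosolic ribosomal protein genes had a median of -0.051 (adjusted p = 0.364), with RPS27 at -0.33 and RPL30 at -0.15. Markers of other cell types stayed low: fibroblast (median 0.077, adjusted p = 0.199, DCN 0.12, COL1A2 0.098), melanocyte (0.13, 0.227, TYR 0.19, PMEL 0.13) and endothelial markers (0.071, 0.436, CDH5 0.38, VWF 0.071) held 1 gene above background among them. With 1 array left out, these medians ran from 0.038 to 0.13, 0.068 to 0.17 and -0.021 to 0.16. Apart from that 1 gene these markers lay below the signal limit, so the size of their differences is not determined. Immune cell markers had a median of 0.19 (0.12 to 0.25 with 1 array left out, adjusted p = 0.164), with PTPRC, the pan-leukocyte antigen, at 3.89 ± 0.10 in mock and 4.09 ± 0.095 in irradiated cells and CD14 at -0.20. CD68, the 1 of 7 above background and named after its value was seen, rose by 0.44 (adjusted p = 0.0334).

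Among single-symbol clusters whose groups did not overlap, the 12 increases with the smallest unadjusted p were DKK1, the Y RNA pseudogene RNY4P4 (1.88, from 5.99 ± 0.24 to 7.86 ± 0.18), MIR1297, MIR4450 (0.77), the 5S rRNA pseudogene RNA5SP294, IGLV3-12, OR10H1, MUCL3, IGHV1-58, CCDC148-AS1, IGHV5-51 and XIRP1. The 12 decreases with the smallest unadjusted p were LINC02035 (-1.07), FASN (-0.98), ZNF322P1 (-0.77), DCAKD (-0.75), LINC00622, ACSL1 (-0.70), PCDHGA10, H1-10, RAB40AL, LINC00667, HUS1B and OR9A4. None passed the unpaired limma test (adjusted p from 0.510 to 0.607). Of these, DKK1 (0.0093), RNY4P4 (0.0093), MIR4450 (0.0209), LINC02035 (0.0093), FASN (0.0258), ZNF322P1 (0.0294), DCAKD (0.0209) and ACSL1 (0.0163) passed the added test, given as adjusted p. The others lay below its signal limit of 6.01, so the size of their differences is not determined and is not given. The mock means of RNY4P4 and MIR4450 also lay just under that limit, so the size of their differences is not determined either. Groups did not overlap for 9424 clusters (13.96%), where chance gives 10%, but for only 861 (9.23%) of the 9324 genes above background. Of all 9324, 312 had an unadjusted p under 0.05 in the unpaired limma test against 466.2 expected by chance. Of the clusters at unadjusted p under 0.05, 3668 of 4822 (76.1%) were higher on the deposited values, 2102 of 3896 (54.0%) after quantile normalization and 1800 of 4380 (41.1%) after median centring, which shifts all clusters of an array alike.

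Among non-coding genes, LINC02035 fell from 7.54 ± 0.21 to 6.47 ± 0.22 and was lower in all 3 pairs. Of 164 microRNA genes above background, 31 were higher and 2 lower at an unadjusted p under 0.05 in the unpaired limma test. Whether the signals of microRNA genes come from mature microRNAs or from longer transcripts was not tested. The 5 non-coding increases with the smallest unadjusted p were MIR3935, MIR1297, MIR4450, MIR3689C and CCDC148-AS1, and the 5 decreases LINC02035, LINC00622, AGAP2-AS1, LINC00667 and SNORD88B, of which only MIR4450 and LINC02035 lay above the signal limit. MIR4748 rose by 0.91 (adjusted p = 0.0093) and MIR181D by 0.85 (adjusted p = 0.0160), both chosen after their values were seen. The mock mean of MIR4748 (6.04 ± 0.22) lay just above the signal limit, so the size of its difference is not determined. The added test called 48 of 495 non-coding genes above background against 389 of 8253 protein-coding genes (Fisher's exact test across genes, p = 9.35e-06), with 17 of 177 long non-coding RNA genes, 21 of 164 microRNA genes and 8 of 117 snoRNA genes. Over all clusters 0 non-coding genes were called by limma, and an unadjusted p under 0.05 was found for 304 of 3526 non-coding (8.62%) and 652 of 18215 protein-coding genes (3.58%, Fisher's exact p = 3.11e-34). With the block the shares were 14.4% and 13.9% (Fisher's exact p = 0.410), and 11.4% for long non-coding RNA genes alone, below the protein-coding share (Fisher's exact p = 0.00197). Non-coding genes were dimmer, with 15.7% above background (median signal 4.36) against 47.3% of protein-coding genes (5.81). Of the 304, 236 were higher, and dim genes as a whole had a median difference of 0.078. Signal level may thus make part of the unpaired contrast, although among genes above background the unpaired shares were 9.90% and 2.82%. Genes are not independent replicates in these tests. Known long non-coding RNAs had a median of -0.047 (adjusted p = 0.428). MALAT1 lay at -0.091 (adjusted p = 0.517), NORAD at -0.50 (adjusted p = 0.0507) and FENDRR below the signal limit, and TERC, the telomerase RNA and the list's 1 call, chosen after its value was seen, fell by 0.66 (adjusted p = 0.0341), lying at -0.23 without irradiated replicate 2 and -0.40 without mock replicate 3.

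At the level of exon parts and splice junctions, single junctions differed widely. Junction JUC04012402.hg.1 went from a mean of 4.56 to 12.90 (adjusted p = 0.0495), and JUC09000488.hg.1 from 4.91 to 9.41 (adjusted p = 0.0292). Junction JUC03015278.hg.1 went from 13.30 to 7.66 (adjusted p = 0.0292) and JUC13002180.hg.1 from 9.80 to 4.84 (adjusted p = 0.0315). The means of 4.56, 4.91 and 4.84 lie below the background limit of 6.01, so the size of these 3 differences is not determined. The genes of these features were not analysed here. These calls came from the paired limma test over 400476 features above background, added after the data were examined, which called 3759 features, 2177 higher and 1582 lower, while the unpaired test over the same features called 0 (27780 at unadjusted p under 0.05). It called 1.71% of 161211 junctions and 0.417% of 239265 exon parts. The planned tests over all features called 0, unpaired (lowest adjusted p = 0.539, 67402 at unadjusted p under 0.05) and paired (lowest adjusted p = 0.143, 128687). The share of increases was 66.6% after quantile normalization (3989 calls, 3502 shared), and the test called 5712, 72 and 2960 features without pair 1, 2 and 3.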

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

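The tests of genes and features above background, their alternatives, the list fit with block and quantile normalization together and the histone list with H2BC10 were chosen only after the results were seen; the other alternatives were planned. Of the alternatives to single-gene differences, 1640 kept their direction and side of the threshold and 29 turned, and of those to shifts of the lists reported 212 kept both, 41 turned, 22 gained a call and 16 lost one. Signal over background limited the tests, as 9324 of 22411 genes lay above the brightest background set. Where a result changed, the cause was not tested unless named.

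Calls over all clusters stayed at 0 under the block, each left-out replicate, the signal filter, both scalings, the eBayes settings, array weights, the equal-variance test (5268 at unadjusted p under 0.05) and the mean of clusters per symbol, all with limma except the equal-variance test. With the replicate block 10237 clusters had an unadjusted p under 0.05. At unadjusted p and at least 2-fold there were 105 clusters and 24747 exon-level features. The block changed the calls of 2 lists, non-homologous end joining (0.0346) and mesenchymal and matrix genes (5.62e-04), and no other list call. With block and tests restricted to genes above background, 467 genes were called. These became 203 with quantile normalization (58.6% higher), 179 with cyclic loess (64.8%), 269 centred on these genes (66.9%), 252 at a limit of 5, 304 at a limit of 8, 812 with array weights, and 66 to 251 without a pair, with fewer samples. Bright exon-level calls ran from 72 to 5712 without a pair.

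For lists (adjusted p for calls, otherwise medians), estimated correlation called 0, with 0.796 for mitosis and 0.639 for histones, interferon, secreted NF-kB and cholesterol genes. fry, which tests each set alone, also called 0: mitosis 0.919, histones 0.419, interferon 0.361, secreted NF-kB genes 0.419, cholesterol 0.483. With the block fry called 1 list, mesenchymal and matrix genes (0.0186). With H2BC10 the histone list gave 3.44e-06. Mitosis was lost with quantile normalization (0.322, median from -0.20 to -0.089) and against bright genes, here those above the median signal (0.512). Mesenchymal genes passed with median centring (0.0403), against bright genes (3.68e-04, median 0.51 over the members above that limit) and with block and quantile normalization (4.96e-04). Epidermal differentiation passed with median centring (0.0403) and against bright genes (0.0153), and DNA replication against bright genes (0.00573) and with block and quantile normalization (0.00165). The median of class I genes became -0.024 with median centring, -0.031 with quantile normalization, with or without the block, -0.052 over bright genes and -0.020 with the mean of clusters. Quantile normalization, with or without the block, turned homologous recombination to 0.078, wound genes to 0.035, unfolded protein genes to 0.018, ribosomal proteins to 0.022 and endothelial markers to -0.0049. Median centring turned VWF (-0.0043) and MDM2 (-0.052), quantile normalization VWF (-0.0049) and CCNB1 (0.041), and array weights KRT1 (0.13).

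Leaving out each array in turn, between 5 and 10 lists were called, the latter without mock replicate 3. These fits were unpaired and kept the partner of the array left out, so differences between cultures entered them. Adjusted p ran from 6.56e-07 to 0.840 for mitosis, 0.00255 to 0.415 for end joining, 0.00117 to 0.289 for secreted NF-kB genes and 0.00924 to 0.289 for mesenchymal genes. Medians ran from -0.034 to -0.25 for end joining and 0.086 to 0.19 for mesenchymal genes. Lists that gained a call were mesenchymal genes without mock 1 (0.0142) and irradiated 3 (0.00924), end joining without irradiated 2 (0.00327) and mock 3 (0.00255), epidermal differentiation without irradiated 1 (0.0486), irradiated 2 (0.0108) and mock 3 (0.000879), unfolded protein genes without irradiated 1 (0.0486) and mock 3 (0.0114), homologous recombination without irradiated 2 (0.0124) and mock 3 (0.000810), DNA replication without mock 2 (0.00253) and mock 3 (0.0114), class I genes without mock 3 (0.00430), and ribosomal proteins without irradiated 3 (0.00924). Other medians ran from -0.12 to 0.31 for DNA replication, -0.36 to 0.18 for homologous recombination, -0.14 to 0.11 for class I genes, -0.012 to 0.28 for epidermal differentiation, -0.12 to 0.011 for basal genes, -0.51 to 0.15 for wound genes, -0.30 to 0.16 for unfolded protein genes, -0.41 to 0.21 for NRF2 targets, -0.18 to 0.063 for ribosomal proteins, -0.11 to 0.025 for long non-coding RNAs, -0.021 to 0.16 for endothelial, 0.038 to 0.13 for fibroblast, 0.068 to 0.17 for melanocyte and 0.12 to 0.25 for immune cell markers. Quantile normalization left fibroblast markers at 0.0042, melanocyte markers at 0.047 and immune cell markers at 0.11. Single genes ran from -0.0073 to 0.18 (XRCC3), -0.25 to 0.024 (RPL30), -0.043 to 0.12 (MDM2), -0.24 to 0.049 (GDF15), -0.16 to 0.12 (CCNB1), -0.68 to 0.15 (KRT5), -2.12 to 1.36 (KRT10), -4.13 to 2.97 (KRT1), -0.46 to 0.34 (MALAT1), -0.14 to 1.68 (FN1), -0.50 to 1.51 (CDH2), -0.11 to 1.22 (FLG), -0.66 to 0.023 (DDIT3) and -1.35 to 0.26 (AKR1C3). A detection p filter and differential exon use were not run.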

Other observations

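Tests of the gene groups, of scaling, of a single pair, of S phase and of RNA yield were chosen only after the results were seen, while the counts over other splits of the arrays were planned except those for the block and for genes above background.

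Further interferon-stimulated genes outside the fixed list were higher in 25 of 27 cases, with a median of 0.44 and 13 called upward among 24 above background, and the paired camera test after quantile normalization gave an adjusted p of 3.17e-15. RSAD2, an antiviral enzyme, rose by 1.74 (adjusted p = 0.0160), whereas GBP2 (-0.82) and TNFSF10 (-0.63) fell and lay at -0.29 and -0.14 without irradiated replicate 2. Genes of fatty acid synthesis and its regulator SREBP1 were lower in 15 of 18 cases (median -0.31, after quantile normalization -0.23, adjusted p = 2.19e-06), 1 of them, ME1, also being in the NRF2 list. SREBF1, which encodes SREBP1, fell by 0.70 and MID1IP1, an activator of acetyl-CoA carboxylase, by 0.63, SREBF1 lying at -0.25 without mock replicate 3. Growth factors and secreted regulators were higher in 18 of 24 cases (median 0.10, adjusted p = 8.52e-05), but not in the unpaired camera test (adjusted p = 0.154). These lists were assembled after seeing the genes called, so their shifts are no independent evidence. They were tested with the preset correlation only, and 0 of the 22 fixed lists passed with an estimated one. CYP24A1, the vitamin D hydroxylase, rose by 1.61, from 7.56 ± 1.58 to 9.17 ± 1.41 (SD, n = 3 per group), and lay at 0.80 without mock replicate 3.

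Pseudogenes of 5S rRNA, transcribed in their functional form by RNA polymerase III, were higher in 328 of 488 cases. Their median of 0.075 fell to 0.048 after quantile normalization. The paired camera test after that normalization gave an adjusted p of 0.00176, with the preset correlation only. Of the 488, 121 lay above background, and the added test called 8 of these upward and 1 downward. Dim genes as a whole had a median of 0.078, and the pseudogenes share sequence. Y RNA genes and pseudogenes had a median of 0.074 (adjusted p = 0.652).

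The rise of interferon-stimulated genes was weighed against scaling and a single deviating pair. After quantile normalization the list median was 1.18 (SD of 0.432 over pairs), which argues against scaling as its whole cause. The lowest pair median was 0.651, which argues against a rise from 1 pair. A response to radiation stays open as a hypothesis, which was not tested apart from these.

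The fall of replication-dependent histone genes may have several sources. After quantile normalization the list still passed the unpaired camera test (adjusted p = 0.000473) with a median of -0.431, or -0.393 as the mean over pairs (SD of 0.295). Set against the SD over pairs, the limit chosen for this check was met with the first value but not with the second. The check therefore does not decide whether scaling is the whole cause of the fall, and a part from scaling stays open. Fewer cells in S phase would lower DNA replication genes, whose pair medians averaged 0.0950 (SD of 0.291 over pairs), too wide a spread to decide. A lower yield of RNA without poly(A) tails would lower snoRNAs, and the 117 snoRNA genes above background averaged -0.116 (SD of 0.172), which does not decide either.

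The excess of decreases among genes above background is in line with a signal-dependent shift between arrays. Dim genes had a median difference of 0.078 and bright genes of -0.089 on the deposited values, and 0.0057 and -0.015 after quantile normalization, when 58.6% of the calls were increases. A true fall of abundant transcripts would give the same picture and was not tested. The 8 hybridisation and labelling control sets, at a median signal of 9.38, also had a median difference of -0.23, but are too few to decide.

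Splitting the 6 arrays into 3 and 3 gives 10 splits, too few for a share under 0.05. All 10 splits called as many clusters as the real one (0, highest other 0), and 4 had as many clusters at unadjusted p under 0.05 (4822, highest other 9530, and 1705 among the 3 other splits that part every pair). As many lists moved in 8 splits (5, highest other 11, and 6 among those that part every pair), and in 6 with the block (7, highest other 13). As many exon-level features reached unadjusted p under 0.05 in 3 splits (67402, highest other 102095, and 22982 among those that part every pair). The paired test of genes above background called 467 in the real split, and 1 split, the real one, called as many (highest other 0). Splits that do not part every pair leave only 1 pair to inform the paired test. The 3 others that part every pair put any real difference into the residual spread. The 0 calls of other splits therefore say little. The splits with more clusters or exon features than the real one do not part every pair, while the split with 13 lists does.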
